A study of Mus musculus with 4 samples.

How the data were processed

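Expression was measured in 4 samples, PBS replicates 1 and 2 and G-CSF replicates 1 and 2, each on 1 Affymetrix mouse genome array of 45101 probe sets. Total RNA was purified with RNeasy, and 40 ng were amplified and labelled with the 3' IVT Express kit. The deposited intensity values are MAS5 signals on a linear scale, computed by the authors for each probe set and scaled per array, and the MAS5 version is not given in the sources used here. The 2% trimmed mean was 500 on each array, so the scaling was left as it was. The samples were grouped by the treatment in the labels, and 0 columns were left without a sample.

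A pseudocount of 23, set from the median of all values (92.9, divided by 4 and rounded), was added before taking log2. The 64 control probe sets were left out of the tests, as were 932 probe sets that list several genes and 9160 that list none. The other 34945 list 1 gene each. Symbols were taken from the platform table and matched by Entrez ID to a mouse gene table. Each of 18193 genes was represented by its probe set with the highest mean signal, and 12187 genes with a mean signal above 95.0, the median of all non-control probe sets, were tested. For 1719 of 4936 genes with several probe sets above the filter, the probe sets lay on both sides of 0.

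Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and a prior of 3.13. Genes at least 2-fold apart with no overlap of the groups were counted for the treatment and for the other splits of the arrays into pairs. The 39 lists with at least 5 tested members were tested with camera at a correlation of 0.01, adjusted over the lists, with camera at a correlation estimated per list and fry beside it. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, here 2, and fewer with an array left out. A pass is then hard to reach, so a lost call in that setting cannot tell correlated genes from few arrays. The lists, the tests and the rule for named genes were fixed before the data were examined. By that rule the text names up to 10 genes per direction with the largest change among those that pass, filled from genes with no overlap and an unadjusted p below 0.01, then up to 4 members of each list with the smallest p, and a fixed set of genes. Genes outside the rule are said to be picked later.

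The background of an array was the highest signal of 27 control probe sets for sequences not added to the sample (106, 94.6, 86.4 and 63.0 in the order above), a limit chosen after the data were seen. Where a group lay below it on both arrays, the fold is given as a lower bound. At background lay 8.63, 4.22, 2.63 and 1.13 percent of tested genes.

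Alternatives fixed in advance were quantile normalization, median centring, pseudocounts of 1 and 92, no filter or the 75th percentile, no trend or a robust fit, the mean of all probe sets, specific probe sets only, probe sets in place of genes, the replicate number as a block, each array left out, and the estimated correlation. Array weights, an 8-fold threshold, lists without neutrophil members, and each array left out with an estimated correlation were added after the data were seen. The procedure was tested on 20 simulated data sets of 12187 genes with 2 arrays per group. Of changed genes it called 0.100 percent at 2-fold, 1.70 percent at 4-fold, 66.5 percent at 16-fold and 90.3 percent at 64-fold, so most changes of 4-fold or less were missed. In total 93 unchanged genes were called, a shifted list was called in 19 of 20 data sets, and 0 of 760 unshifted lists were called. The simulated genes were drawn independently and with the same variance in both groups. The estimated correlation was 0.947 in the real cell cycle list, for example. These counts therefore cannot show false list calls where genes move together or an array stands apart. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.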

Results

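By its labels, the series profiled cells of bone marrow origin in the fibrotic liver of C57BL/6 mice. It compared mice with and without granulocyte colony-stimulating factor (G-CSF), a cytokine that drives neutrophil production and releases marrow cells into the blood. Fibrosis was produced with 30 injections of carbon tetrachloride, a hepatotoxin, at 1 ml/kg. Over the last 7 days the mice received recombinant human G-CSF at 100 µg/kg or a vehicle of phosphate-buffered saline (PBS) with mouse serum albumin at 0.1%. The labels name both liver tissue and bone marrow-derived cells as the source, and no sort or gate is given in the sources used here. Total RNA was measured on 4 Affymetrix mouse arrays of 45101 probe sets, 2 for PBS and 2 for G-CSF. The question was which transcripts differed between the G-CSF and PBS samples. The labels do not say that the samples came from separate animals, so limma p-values of single genes measure only the spread between these arrays. The camera p-values of lists at the fixed correlation of 0.01 do not measure that spread. They compare the genes of a list with the other genes and treat genes as nearly independent. The correlations estimated per list ran from −0.093 to 0.947. Differences are G-CSF minus PBS on the log2(signal + 23) scale, with the standard error of the fit (SE, n = 2 arrays per group). This scale understates the change of weakly expressed genes. Square brackets give the same difference against PBS replicate 1 alone and PBS replicate 2 alone, for values that 1 PBS array moves by over 1.5 times.

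RNA quality ratios were far above 1 on all 4 arrays and separated the groups. The ratio of the 3' to the 5' Gapdh control probe set was 15.7 and 14.8 in PBS replicates 1 and 2, and 20.2 and 19.1 in G-CSF replicates 1 and 2. The Actb ratio was 11.2 and 9.88 in the PBS arrays and 12.6 and 13.7 in the G-CSF arrays. Both ratios were thus higher on both G-CSF arrays, the arrays on which the lists below that rose were higher, and a separation of the groups in either direction arises in 1 of 3 splits by chance. Albumin (Alb), the main secreted hepatocyte protein, had signals of 43301 and 46068 with PBS and 52315 and 46302 with G-CSF. The highest signals of any probe set on the arrays were 58436 to 63693. Alb was thus near the top of the range on each array, where a difference may be compressed. Cyp2e1 and Ambp, also in the hepatocyte list, had signals of 11204 to 32028 and 14192 to 34388. Hepatocyte transcripts were thus abundant on all 4 arrays, and the share of RNA from cells of bone marrow origin was not measured. PBS replicate 1 stood apart from the other arrays. Its Pearson correlation with them over 12187 genes was 0.813 to 0.844, against 0.939 and 0.941 between PBS replicate 2 and the G-CSF arrays and 0.974 between the G-CSF arrays. It held 241 genes at least 4-fold above all other arrays and 48 at least 4-fold below all of them, while each other array held at most 3 above and 21 below. The SD between replicates was 0.82 on the log2 scale with PBS and 0.29 with G-CSF.

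Neutrophil transcripts were far higher in both G-CSF arrays. Of 44 tested genes in 3 neutrophil lists, 38 were at least 2-fold higher with no overlap of the groups, and 26 were at least 8-fold higher. The list of primary granule proteins, which promyelocytes make, rose by a median of 4.26 over 8 genes (limma camera, adjusted p = 1.02e-17; adjusted p = 0.259 with an estimated correlation). Mpo, myeloperoxidase, was 104-fold higher (log2 difference 6.71 ± 0.46), with signals of 166 and 96.4 against 11636 and 21026. Ctsg, cathepsin G, was not above background in PBS and at least 81.9-fold higher. Prtn3, proteinase 3, was higher by 5.57 ± 0.56, Elane, neutrophil elastase, by 4.11 ± 0.47, Ms4a3 by 4.24 ± 0.33 and Serpinb1a by 4.28 ± 0.38 (3.17 by another probe set). Elane was above background on 1 of the PBS arrays. The list of secondary and tertiary granule proteins, made in myelocytes to band cells, rose by a median of 3.77 over 18 genes (adjusted p = 7.30e-30; adjusted p = 0.259 with an estimated correlation). Its median was 3.28 with the genes at background set to their bound and 3.09 with 4 times the pseudocount. Its members Ltf, lactoferrin, Camp, cathelicidin, and Ngp were higher by 5.51 ± 0.82, 5.48 ± 0.69 and 5.09 ± 0.92. Chil3, Cd177 and Pglyrp1 were higher by 5.67 ± 0.41, 5.95 ± 0.56 and 4.89 ± 0.32. Cd177 was above background on 1 of the PBS arrays only. Pglyrp1, with PBS signals of 110 and 101, lay little above background on both, as did Mpo on PBS replicate 2. The sizes of these differences thus rest on PBS signals near background. The list of mature neutrophil markers rose by a median of 3.51 over 18 genes (adjusted p = 2.08e-34; adjusted p = 0.259 with an estimated correlation). Its median was 3.27 with bounds and 2.90 with 4 times the pseudocount. Csf3r, the G-CSF receptor, was 14.6-fold higher (3.87 ± 0.36), and Cxcr2, a chemokine receptor, was at least 8.51-fold higher from a PBS level at background. The calgranulins S100a8 and S100a9 were higher by 2.63 ± 0.55 and 4.76 ± 0.62, Stfa2l1 by 4.53 ± 0.34 and Trem3 by 3.69 ± 0.36. The S100a8 signals with G-CSF, 63074 and 56036, lay near the highest of those arrays, so its difference may be understated.

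**Figure D1:**
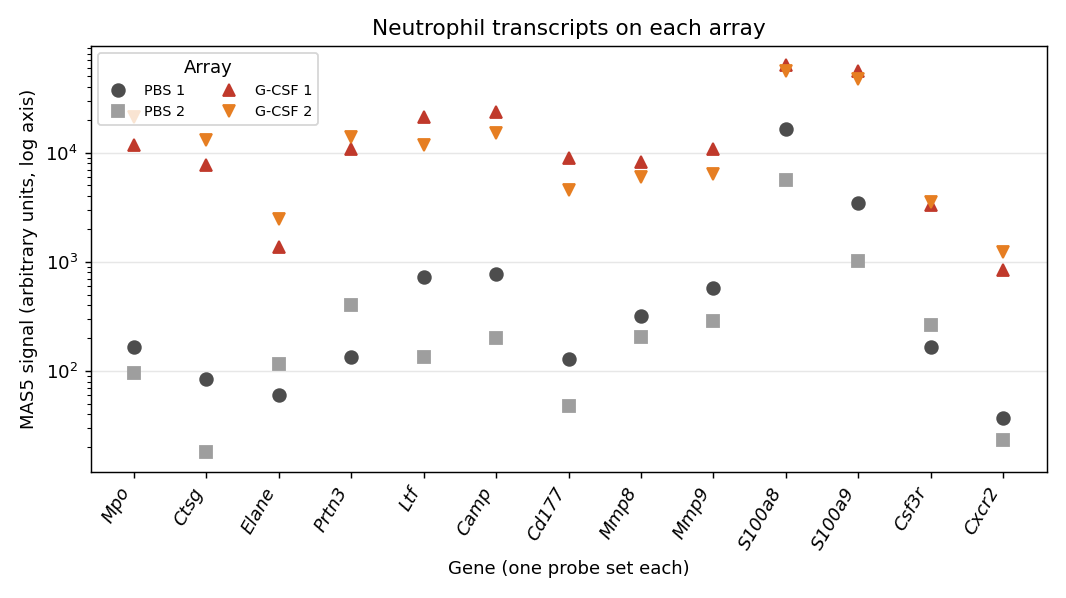
MAS5 signal in arbitrary units, on a log axis, of 13 neutrophil genes on each of the 4 arrays, with 1 marker per array and no averaging. Both G-CSF arrays lie above both PBS arrays for each gene shown, with Mpo at 11636 and 21026 against 166 and 96.4.

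The neutrophil result did not rest on either PBS array. Against PBS replicate 1 alone the medians of the primary granule, secondary granule and mature lists were 4.48, 3.60 and 3.30, and against PBS replicate 2 alone they were 4.16, 3.74 and 3.33. Each list kept its call with any 1 array left out at the fixed correlation, and none did with an estimated correlation. The latter setting rests on the few residual degrees of freedom, so it cannot tell whether the lists depend on 1 array. Both Gapdh and Actb ratios were also higher on the G-CSF arrays. Adjusted over the list alone, 6, 14 and 16 of their members passed, all higher, whereas 0 passed over all 12187 genes. They were also the only lists past fry, a self-contained rotation test (adjusted p = 0.0477 each).

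Over all genes, 0 genes were called higher and 0 lower by limma after Benjamini-Hochberg adjustment. The unadjusted p was below 0.05 for 429 genes, 382 higher and 47 lower, and the smallest adjusted p was 0.0676. With array weights, added after the data were seen, 33 genes were called higher and 0 lower. At an adjusted p below 0.1 there were 16 genes, all higher, and 12 of them belong to the neutrophil lists. Calls depended on single arrays. Without PBS replicate 1, 339 genes were higher and 177 lower; without PBS replicate 2, 2753 and 1936; without G-CSF replicate 1, 6 and 0; and without G-CSF replicate 2, 22 and 0. Cd177, Chil3, Ctsg, Mpo, Pglyrp1 and Prtn3 were called higher in all 4 of these fits. With 2 arrays against 2, an exact permutation test of a single gene cannot go below a two-sided p of 0.333.

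By size, 677 genes differed at least 2-fold with no overlap of the groups, 492 higher and 185 lower with G-CSF. The other 2 ways to split the arrays into pairs gave 632 and 836, so the number of such genes did not set the treatment apart. At least 8-fold, the treatment gave 54 genes, 51 of them higher, against 12 and 10 in the other splits. Of all genes, 30.7% had groups with no overlap, where chance gives 33.3%. Without PBS replicate 2 the 2-fold count was 3356. Outside the neutrophil lists, the largest computed differences were those of Ifitm6 (5.30 ± 0.42) and Ceacam10 (4.94 ± 0.50, and 3.55 by another probe set). Ceacam10 had PBS at background and a fold of at least 15.9, so its rank is not known. Asprv1, for example, differed by 4.50 ± 0.36 with PBS above background. None of these 3 passed the adjusted threshold. On the lower side only 2 genes combined no overlap with an unadjusted p below 0.01. These were Phlda1 (−1.39 ± 0.34) and the predicted gene 2610316D01Rik (−2.02 ± 0.49), and neither passed the adjusted threshold. Over the alternative settings the latter ran from −2.59 to −1.23.

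Other leukocytes of the myeloid lineage moved less. The monocyte marker list rose by a median of 0.37 [0.77, 0.48] over 15 genes (adjusted p = 0.000121; adjusted p = 0.436 with an estimated correlation), and 4 members passed adjusted over the list alone. F13a1, the factor XIII A chain carried by monocytes, was higher by 3.70 ± 0.64 and Ccr2, the receptor that brings monocytes out of the marrow, by 1.71 ± 0.42, while another Ccr2 probe set gave 0.90. Vcan, versican, was higher by 1.93 ± 0.37, while another Vcan probe set gave 0.66. The list also holds Chil3, a neutrophil gene, and without it the median was 0.27 (adjusted p = 0.00302). The list of mast cell, basophil and eosinophil genes rose by a median of 0.99 over 6 genes, or 0.46 with bounds (adjusted p = 0.00322; adjusted p = 0.440 with an estimated correlation). With no filter on low values its median was 0.0070 (adjusted p = 0.0291), and with 4 times the pseudocount 0.63 (adjusted p = 0.00285). Its call was lost without PBS replicate 2 (median 1.40, adjusted p = 0.157). Siglecf, an eosinophil lectin, and Mcpt8, a basophil protease, were at least 4.54-fold and at least 1.97-fold higher from PBS levels at background, and these 2 passed adjusted over the list alone. Tissue macrophage markers did not pass (median 0.28 over 21 genes, adjusted p = 0.126). Adgre1, which encodes F4/80, differed by 0.28 ± 0.47 [0.82, −0.27] and Cd68 by 0.78 ± 0.50 [1.40, 0.15]. Kupffer cell markers, genes of the resident liver macrophages, did not pass either (median −0.01 over 16 genes, adjusted p = 0.312), with Clec4f at −0.09 ± 0.64 [0.80, −0.99] and Adgre4 at −0.95 ± 0.61 [−0.11, −1.79]. Both macrophage lists depended on the PBS array. Without PBS replicate 1 they were lower with G-CSF, by a median of −0.27 (adjusted p = 0.00359) and −0.66 (adjusted p = 1.57e-06), with an adjusted p of 0.703 for both with an estimated correlation. Without PBS replicate 2 their medians were 0.83 (adjusted p = 0.000101) and 0.58 (adjusted p = 0.0579), with an adjusted p of 0.550 for both with an estimated correlation. Without G-CSF replicate 2 the Kupffer median was 0.07.

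T cell transcripts set PBS replicate 1 apart. The median signal of the 18 tested T cell markers was 1686 there, against 122 in PBS replicate 2 and 217 and 129 in the G-CSF arrays. In PBS replicate 1, 15 of the 18 lay more than 2-fold above all other arrays. Cd247, the zeta chain of the T cell receptor complex, had a signal of 2570 there and 78.5 to 104 elsewhere, Cd28 had 1636 against 15.1 to 106, and Cd8b1 had 1165 against 56.4 to 89.6. The list as a whole fell with G-CSF by 1.34 (median −1.34, adjusted p = 0.000796; adjusted p = 0.728 with an estimated correlation), and by −1.29 with bounds. Without PBS replicate 1 the direction turned, with a median of 0.36 (adjusted p = 0.0445; adjusted p = 0.703 with an estimated correlation), and without PBS replicate 2 the median was −3.56. The call was also lost with the 75th percentile filter (adjusted p = 0.0814). Among NK and cytotoxic genes the median was 0.38 over 10 genes (adjusted p = 0.167), and it was −0.07 without PBS replicate 1 and 1.03 without PBS replicate 2. Gzma, granzyme A, had a signal of 34946 in PBS replicate 1 and 111 to 301 elsewhere. Nkg7 differed by 1.22 ± 0.34, and Gzmk, with PBS at background, differed by at least 1.64-fold.

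**Figure D2:**
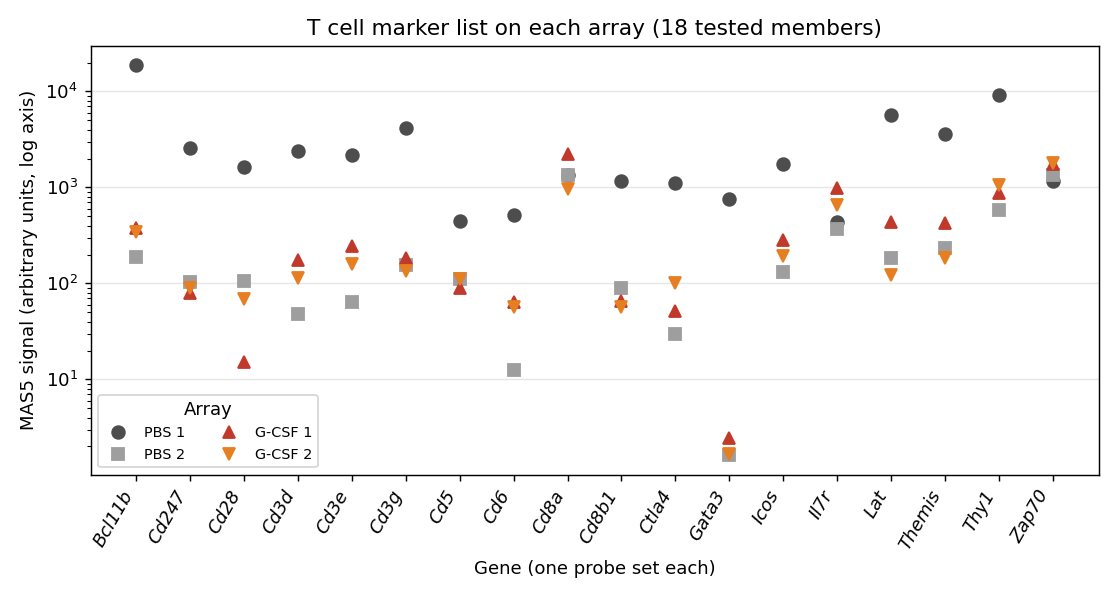
MAS5 signal in arbitrary units, on a log axis, of the 18 tested genes of the T cell list on each of the 4 arrays, with 1 marker per array. For 15 of the 18 genes PBS replicate 1 lies more than 2-fold above the other arrays, which lie close together for most genes.

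B cell and plasma cell lists rose by medians of 0.64 [1.13, −0.07] over 18 genes and 0.70 [1.12, −0.10] over 9 genes (adjusted p = 0.0235 and 0.0207; adjusted p = 0.728 with an estimated correlation for both). Without PBS replicate 1 the medians were −0.07 and −0.10, and the calls were lost (adjusted p = 0.925 and 0.601). The B cell call was also lost without G-CSF replicate 1 (median 0.36, adjusted p = 0.217) and with the 75th percentile filter (adjusted p = 0.459). The plasma cell call was lost with that filter (adjusted p = 0.157) and with specific probe sets only (adjusted p = 0.132). Cr2, a complement receptor of B cells, differed by 1.42 ± 0.52 [1.95, 0.89], and Fkbp11, a secretory chaperone of plasma cells, by 1.61 ± 0.51. Over the alternative settings the Fkbp11 difference was 0.61 at its lowest. Igha, the IgA heavy chain, had signals of 2597 and 33051 with PBS and 18034 and 31161 with G-CSF. The dendritic cell and MHC class II list did not pass (median 0.22 [0.49, −0.06] over 18 genes, adjusted p = 0.167; median −0.06 without PBS replicate 1), with Cd74, the invariant chain, at 0.67 ± 0.33. Erythroid genes did not pass (median 0.07 [0.36, −0.10] over 9 genes, adjusted p = 0.576), with Klf1, an erythroid transcription factor, at −0.48 ± 0.48 (−0.85 and −0.10 without G-CSF replicates 1 and 2). Their median was −0.10 without PBS replicate 1 and −0.04 without G-CSF replicate 1. Megakaryocyte and platelet genes rose by a median of 0.82 over 14 genes (adjusted p = 0.000121; adjusted p = 0.728 with an estimated correlation). That call was lost without PBS replicate 1 (0.65, adjusted p = 0.0693) and without G-CSF replicate 1 (0.51, adjusted p = 0.0937), and without G-CSF replicate 2 the median was 1.83 (adjusted p = 6.18e-20; adjusted p = 0.856 with an estimated correlation). Ppbp, a platelet chemokine, had a signal of 4489 in G-CSF replicate 1 and 280 in G-CSF replicate 2, against 109 and 159 with PBS. Vwf, von Willebrand factor, differed by 1.32 ± 0.56 [2.05, 0.58]. Stem and progenitor genes rose by a median of 0.41 over 17 genes (adjusted p = 0.0156; adjusted p = 0.728 with an estimated correlation). Lmo2, a regulator of blood progenitors, differed by 1.36 ± 0.50 [1.98, 0.74]. This call was lost without PBS replicate 1 (0.21, adjusted p = 0.0984), PBS replicate 2 (0.80, adjusted p = 0.236) or G-CSF replicate 2 (0.47, adjusted p = 0.0557), and with the 75th percentile filter (0.12, adjusted p = 0.562).

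Extracellular proteases rose as a list, by a median of 0.54 [1.00, 0.02] over 20 matrix metalloproteinase and ADAM genes (adjusted p = 3.40e-05; adjusted p = 0.665 with an estimated correlation). Mmp8, neutrophil collagenase, was 25.3-fold higher (4.66 ± 0.39) and Mmp9, gelatinase B, 19.2-fold higher (4.27 ± 0.49, and 5.20 by another probe set). Mmp8 and Mmp9 were the 2 members that passed adjusted over the list alone. Adam8 and Mmp3, stromelysin 1, differed by 1.68 ± 0.42 and 1.41 ± 0.51 [0.85, 1.97]. Mmp13, a rodent interstitial collagenase, lay below the filter on low values, with signals of 32.4 and 63.8 with PBS and 50.7 and 53.3 with G-CSF. Without Mmp8 and Mmp9 the median was 0.51 (adjusted p = 0.00479). Without PBS replicate 1 the median was 0.02 and the call was lost (adjusted p = 0.126). Protease inhibitors and plasmin system genes rose by a median of 0.72 [1.11, 0.71] over 13 genes, or 0.62 with bounds (adjusted p = 4.50e-07; adjusted p = 0.603 with an estimated correlation). At the fixed correlation each array could be left out without losing that call, and with an estimated correlation it was lost in each of these fits. Adjusted over the list alone, 3 members passed: Serpinb1a, also in the primary granule list, Slpi and Cst7. Serpinb1a was higher by 4.28 ± 0.38 (3.17 by another probe set). Slpi, an inhibitor of neutrophil elastase, was higher by 2.94 ± 0.60. Cst7, a cystatin of leukocytes, was at least 3.72-fold higher from a PBS level at background. Timp1 differed by 0.72 ± 0.31 and did not pass. Without Serpinb1a the list median was 0.67 (camera adjusted p = 3.93e-05). Lysosomal genes rose by a median of 0.27 [0.70, −0.12] over 23 genes (adjusted p = 0.0207; adjusted p = 0.751 with an estimated correlation). Ctse, cathepsin E, differed by 1.29 ± 0.31. Their call was lost without PBS replicate 1 (median −0.12, adjusted p = 0.155) and without G-CSF replicate 1 (0.21, adjusted p = 0.153), with the 75th percentile filter (adjusted p = 0.0814) and with the mean of all probe sets (adjusted p = 0.0923).

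Collagens rose by a median of 0.43 over 17 chains (adjusted p = 0.00241; adjusted p = 0.728 with an estimated correlation), and 16 of the 17 had a difference above 0. Col1a2 differed by 0.55 ± 0.31, and by 0.32 without G-CSF replicate 2. Col1a1 differed by 0.34 ± 0.44 [0.74, −0.06], with 1.14 by another probe set, and by −0.06 without PBS replicate 1. The collagen call was lost without PBS replicate 1 (0.34, adjusted p = 0.117) and without G-CSF replicate 2 (0.16, adjusted p = 0.379). Stellate cell and myofibroblast genes rose by a median of 0.51 [0.93, −0.04] over 27 genes (adjusted p = 0.000722; adjusted p = 0.728 with an estimated correlation), and their call was lost without PBS replicate 1 (−0.04, adjusted p = 0.880). Acta2, smooth muscle actin, differed by 1.24 ± 0.37 and Vim, vimentin, by 1.20 ± 0.31, each higher in both G-CSF arrays than in both PBS arrays. Over the alternative settings the Acta2 difference was 0.54 at its lowest. Fibrogenic growth factors and receptors rose by a median of 0.33 [0.66, 0.01] over 20 genes (adjusted p = 0.0234; adjusted p = 0.728 with an estimated correlation). Lgals3, galectin 3, differed by 1.38 ± 0.40. Tgfb1 differed by 0.69 ± 0.40, with −0.33 by another probe set. The call was lost without PBS replicate 1 (0.01, adjusted p = 0.778) and without G-CSF replicate 2 (0.24, adjusted p = 0.0755), with the 75th percentile filter (0.25, adjusted p = 0.157) and with the mean of all probe sets (0.18, adjusted p = 0.0789).

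Lists of liver cells followed PBS replicate 1. Hepatocyte genes did not pass (median 0.16 over 23 genes, adjusted p = 0.178), with Alb at 0.14 ± 0.23 and Cyp2e1, an ethanol-inducible P450 that activates carbon tetrachloride, at 0.48 ± 0.54 [1.24, −0.27]. Their median was 0.91 without PBS replicate 2 (adjusted p = 9.28e-06) and −0.38 without PBS replicate 1 (adjusted p = 2.51e-05). Without G-CSF replicate 2 it was 0.29 (adjusted p = 0.0310). With an estimated correlation the adjusted p in these 3 fits was 0.550, 0.703 and 0.856. Liver endothelial genes rose by a median of 0.37 [0.93, −0.21] over 25 genes (adjusted p = 0.0125; adjusted p = 0.751 with an estimated correlation). Fcgr2b, the Fc receptor of sinusoidal endothelium, differed by 0.93 ± 0.51 [1.56, 0.29], with 1.34 by another probe set. The call was lost without PBS replicate 1 (−0.21, adjusted p = 0.120) and without G-CSF replicate 2 (0.23, adjusted p = 0.249), and the median was 0.57 without G-CSF replicate 1. Bile duct genes did not pass (median 0.42 over 12 genes, adjusted p = 0.162), with Krt19 at 0.67 ± 0.50 [1.16, 0.18]. Their median was −0.27 without PBS replicate 1, and they passed without PBS replicate 2 (1.08, adjusted p = 0.0113) and without G-CSF replicate 1 (0.58, adjusted p = 0.0144), but not with an estimated correlation (adjusted p = 0.550 and 0.896). Hepatocyte growth and angiogenic factors did not pass (median 0.40 over 15 genes, adjusted p = 0.126), nor with the 75th percentile filter or the mean of all probe sets (0.64 and 0.24, adjusted p = 0.0988 and 0.390), with Hgf at 0.17 ± 0.55 [0.83, −0.49]. Their median was −0.32 without PBS replicate 1, and they passed without PBS replicate 2 (1.07, adjusted p = 0.00519) and without G-CSF replicate 1 (0.44, adjusted p = 0.0483), but not with an estimated correlation (adjusted p = 0.550 and 0.896).

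**Figure D3:**
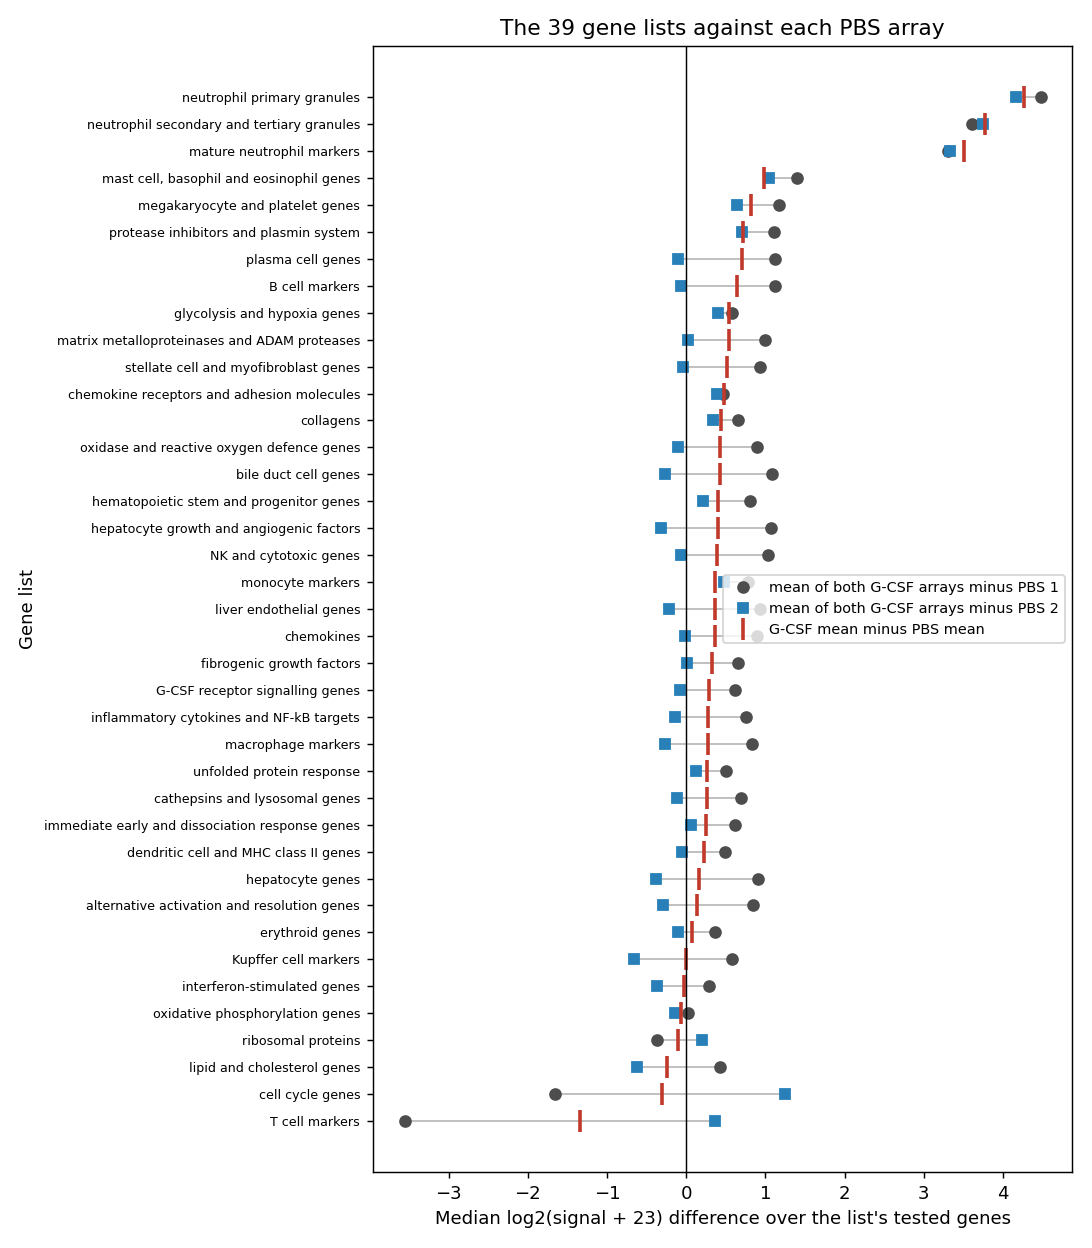
Median difference in log2(signal + 23) over the tested genes of each of the 39 lists, one line per list, with circles for both G-CSF arrays against PBS replicate 1, squares for the same against PBS replicate 2, and bars for the group difference. The 3 neutrophil lists lie between 3.30 and 4.48 against either PBS array, while T cell markers run from −3.56 to 0.36 and cell cycle genes from −1.65 to 1.25.

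Receptors of leukocyte migration rose by a median of 0.47 over 20 genes (adjusted p = 0.000645; adjusted p = 0.440 with an estimated correlation). Of these, 4 passed adjusted over the list alone: Cxcr2, also a mature neutrophil marker, Ccr1, Itgb2 and Ccr2. Ccr1 was higher by 2.41 ± 0.32 and Itgb2, the leukocyte integrin beta 2 chain, by 1.34 ± 0.32. Without Cxcr2 the list median was 0.36 (camera adjusted p = 0.00651). Cxcr4, which retains cells in the marrow, had signals of 2293 and 242 with PBS and 1101 and 1198 with G-CSF. The call was lost without PBS replicate 2 (0.47, adjusted p = 0.0864). The median was 0.26 without G-CSF replicate 1 and 0.23 with the 75th percentile filter (adjusted p = 0.00920). Chemokines rose by a median of 0.36 [0.90, −0.02] over 22 genes (adjusted p = 0.00915; adjusted p = 0.728 with an estimated correlation), and by 0.74 with the 75th percentile filter (adjusted p = 0.00182). The chemokine call was lost without PBS replicate 1 (−0.02, adjusted p = 0.880). Ccl8, a monocyte chemokine, differed by 1.74 ± 0.38, and Cxcl12, the ligand of Cxcr4, by 0.84 ± 0.50 [1.498, 0.18], with 0.49 by another probe set. Inflammatory cytokines and NF-kB targets rose by a median of 0.28 [0.75, −0.14] over 25 genes (adjusted p = 0.0435; adjusted p = 0.735 with an estimated correlation). That call was lost without PBS replicate 1 (−0.14, adjusted p = 0.802). It was also lost with no filter, with the 75th percentile filter, with no trend, with the mean of all probe sets and with specific probe sets only (adjusted p = 0.155, 0.0952, 0.0501, 0.112 and 0.0544). Il1b differed by 1.28 ± 0.39. Saa3, an acute phase protein, had signals of 229 and 1838 with PBS and 7462 and 7197 with G-CSF. Alternative activation genes rose by a median of 0.14 [0.84, −0.29] over 14 genes (adjusted p = 0.0392; adjusted p = 0.728 with an estimated correlation). The 2 that passed adjusted over the list alone were Chil3, also a neutrophil gene, and Retnla, higher by 1.83 ± 0.38. Without the neutrophil members this list did not pass (adjusted p = 0.188), and with all members its call was lost without PBS replicate 1 (−0.29, adjusted p = 0.169). Its median was 0.39 and 0.01 without G-CSF replicates 1 and 2. The call was also lost with the 75th percentile filter (adjusted p = 0.210) and with specific probe sets only (adjusted p = 0.0535). Genes of G-CSF receptor signalling rose by a median of 0.29 [0.62, −0.08] over 23 genes (adjusted p = 0.0169; adjusted p = 0.665 with an estimated correlation). The 2 that passed adjusted over the list alone, Csf3r and Il1r2 (3.59 ± 0.39), are also neutrophil markers, and without such members the list did not pass (adjusted p = 0.239). Cebpd, a myeloid transcription factor, differed by 2.14 ± 0.73 [3.20, 1.08], with 1.01 by another probe set. The call was lost without PBS replicate 1 (−0.08, adjusted p = 0.108) and without PBS replicate 2 (0.62, adjusted p = 0.0805), and with no filter (adjusted p = 0.0556).

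Cell cycle genes changed direction with the PBS array. The list fell by 0.31 (median −0.31 over 43 genes, adjusted p = 0.0102; adjusted p = 0.751 with an estimated correlation), with −0.18 as the mean of all probe sets (adjusted p = 0.0273), yet it was higher by 1.25 without PBS replicate 1 (adjusted p = 2.31e-21; adjusted p = 0.703 with an estimated correlation) and at −1.65 without PBS replicate 2. Its median signal was 3148 in PBS replicate 1, 339 in PBS replicate 2 and 885 and 949 in the G-CSF arrays. In PBS replicate 1, the array with high T cell markers, 36 of the 43 genes lay more than 2-fold above all others. Mki67, the Ki-67 proliferation antigen, had signals of 13571 and 1534 with PBS and 4425 and 5466 with G-CSF, and Mcm2, a replication licensing factor, 5949 and 1840 against 1209 and 770. Ribosomal protein genes did not pass (median −0.10 over 30 genes, adjusted p = 0.0794), with Rps3 at −0.36 ± 0.31 [−0.64, −0.08]. They were higher without PBS replicate 1 (0.19, adjusted p = 0.00359) and lower without PBS replicate 2 (−0.36, adjusted p = 4.67e-05), but did not pass with an estimated correlation (adjusted p = 0.749 and 0.550).

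Glycolysis and hypoxia genes rose by a median of 0.54 over 27 genes (adjusted p = 0.000598; adjusted p = 0.440 with an estimated correlation). Hk3, the hexokinase of myeloid cells, differed by 2.43 ± 0.45, and Pdk1, which restrains pyruvate oxidation, by −1.16 ± 0.38 (−0.49 by another probe set). The call was lost without PBS replicate 2 (0.57, adjusted p = 0.121). Oxidase and reactive oxygen defence genes rose by a median of 0.43 [0.89, −0.11] over 18 genes (adjusted p = 0.00549; adjusted p = 0.728 with an estimated correlation). Their call was lost without PBS replicate 1 (−0.11, adjusted p = 0.821), and the median was 0.26 without G-CSF replicate 1. Ncf1, a subunit of the phagocyte NADPH oxidase, was higher by 2.68 ± 0.46 and was the 1 member that passed adjusted over the list alone, and Cyba, another subunit, differed by 1.18 ± 0.36. Unfolded protein response genes rose by a median of 0.27 [0.51, 0.12] over 22 genes (adjusted p = 0.0156; adjusted p = 0.728 with an estimated correlation), with Asns, asparagine synthetase, at 1.95 ± 0.48 (2.55 by another probe set). That call was lost without PBS replicate 1 (0.12, adjusted p = 0.305) and without G-CSF replicate 1 (0.20, adjusted p = 0.316). Immediate early and dissociation response genes, which tissue handling induces, did not pass (median 0.25 [0.62, 0.07] over 33 genes, adjusted p = 0.0794), with Klf4 at 1.32 ± 0.41 (0.91 by another probe set). They passed with the 75th percentile filter (0.42, adjusted p = 0.0132). With the filter at the median and an estimated correlation, their camera adjusted p was 0.728. Lipid and cholesterol genes fell by 0.24 (median −0.24 [0.43, −0.62] over 25 genes, adjusted p = 0.0137; adjusted p = 0.728 with an estimated correlation). The sterol synthesis enzymes Dhcr7 and Sqle differed by −1.39 ± 0.48 [−0.84, −1.95] and −0.97 ± 0.33. Without PBS replicate 2 the median was 0.43 (adjusted p = 0.309), and without G-CSF replicate 2 it was −0.16 (adjusted p = 0.0552). Without G-CSF replicate 1 it was −0.15. Interferon-stimulated genes fell by 0.03 (median −0.03 [0.28, −0.37] over 36 genes, adjusted p = 0.0477; adjusted p = 0.728 with an estimated correlation). Their members Ifit3 and Ifit2 differed by −1.28 ± 0.34 and −1.05 ± 0.40 [−1.45, −0.66]. The median was 0.28 without PBS replicate 2 (adjusted p = 0.777) and 0.08 without G-CSF replicate 1 (adjusted p = 0.271), and −0.12 without G-CSF replicate 2. The interferon call was also lost with quantile normalization, 4 times the pseudocount, either other filter, the mean of all probe sets, specific probe sets only, the replicate block and without neutrophil members, at adjusted p values from 0.0512 to 0.0992. Oxidative phosphorylation genes fell by 0.07 (median −0.07 [0.02, −0.14] over 39 genes, adjusted p = 0.0477; adjusted p = 0.728 with an estimated correlation), with Sdhc at −0.58 ± 0.38 [−0.24, −0.92] (−0.12 by another probe set). Their call was lost without PBS replicate 2 (0.02, adjusted p = 0.381) and without either G-CSF array (−0.11 and −0.06, adjusted p = 0.143 and 0.246). It was also lost with quantile normalization, 4 times the pseudocount, either other filter, no trend, the mean of all probe sets, the replicate block and without neutrophil members, at adjusted p values from 0.0512 to 0.164.

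In all, 29 of the 39 lists passed, 24 higher and 5 lower with G-CSF, and 0 passed with an estimated correlation. Without PBS replicate 1, 17 passed, and 11 of these kept the call and the direction they had with all arrays. In the lists for which no count is given above, no member passed limma adjusted over the list alone. Of the genes fixed for naming, Ly6g was not analysed here.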

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

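Besides the annotated genes, the array holds probe sets for which the platform table lists no gene, and these entered no comparison of the report. Of 2000 such probe sets above the filter, 63 were at least 2-fold higher in both G-CSF arrays than in both PBS arrays, against 40 at least 2-fold lower. These counts were looked at because they lie in data outside the named genes, and the difference was not tested. They do not set the treatment apart: both directions together gave 103, against 112 and 124 in the other splits of the arrays into pairs. The shares of 3.15 and 2 percent compare with 4.04 and 1.52 percent of the tested genes. The probe set with the highest computed difference toward G-CSF had signals of 23.3 and 82.1 with PBS and 539.8 and 448 with G-CSF, and the next had 2.78 and 19.8 against 193.7 and 166. The PBS signals of both lay below background (106 and 94.6), so the size of their differences and their order are not known. The highest difference of a probe set above background on both PBS arrays was 2.27, with signals of 380 and 877 against 3112 and 2680. All were picked after their values were seen, and no explanation was tested for them.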

How the results depend on the processing

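The settings compared were chosen before the data were examined, except array weights, the 8-fold threshold, the lists without their neutrophil members, and an array left out together with an estimated correlation, which were tests chosen after the results were seen. No gene passed limma in either direction under the alternatives of scaling, pseudocount, filter, variance trend and probe set rule, nor with probe sets in place of genes, where the smallest adjusted p ran from 0.0530 to 0.100 and 266 to 787 genes or probe sets had an unadjusted p below 0.05. Array weights gave 33 higher and 0 lower. The replicate block gave 89 higher and 3 lower; the labels share only the replicate numbers, and same-numbered deviations had a correlation of −0.04. With 1 array left out, 6 to 2753 genes were higher and 0 to 1936 lower, with the lone array of a group assumed to vary like the pair of the other. The count of genes at least 2-fold apart was 378 with the 75th percentile filter, where 7421 genes were tested, 54 at 8-fold, and 843 to 3356 with 1 array left out. The number of lists past camera was 18 of 35 with the 75th percentile filter, 0 with an estimated correlation, 0 with any 1 array left out and an estimated correlation, and 17 to 26 with 1 array left out. With an estimated correlation the primary granule, secondary granule and mature neutrophil lists kept their medians of 4.26, 3.77 and 3.51. The collagens kept 0.43 and the proteases 0.54, and none of these lists passed. A higher correlation is not needed for such a loss, although the estimates ran from −0.093 to 0.947 over the lists. For monocyte markers the estimate was −0.016, below the fixed 0.01, yet the unadjusted camera p went from 1.91e-05 to 0.0448. That setting also rests on the few residual degrees of freedom, and the share of each in the other losses was not tested. With 1 array left out the collagens ran from 0.16 to 0.65 and the proteases from 0.020 to 1.00.

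Of 39 lists, 15 never changed direction, and 28 of 656 comparisons were in the other direction. The Kupffer cell median was 0.0075 at a pseudocount of 1. With 1 array left out, the lists that turned, with their lowest and highest medians, were Kupffer cell markers (−0.66 to 0.58), macrophage markers (−0.27 to 0.83), dendritic cell and MHC class II genes (−0.058 to 0.49), T cell markers (−3.56 to 0.36), NK and cytotoxic genes (−0.071 to 1.03), B cell markers (−0.069 to 1.13), plasma cell genes (−0.10 to 1.12), erythroid genes (−0.10 to 0.36), hepatocyte genes (−0.38 to 0.91), stellate cell and myofibroblast genes (−0.041 to 0.93), liver endothelial genes (−0.21 to 0.93), bile duct cell genes (−0.27 to 1.08), cathepsins and lysosomal genes (−0.12 to 0.70), hepatocyte growth and angiogenic factors (−0.32 to 1.07), chemokines (−0.017 to 0.90), inflammatory cytokines and NF-kB targets (−0.14 to 0.75), alternative activation and resolution genes (−0.29 to 0.84), G-CSF receptor signalling genes (−0.079 to 0.62), interferon-stimulated genes (−0.37 to 0.28), cell cycle genes (−1.65 to 1.25), oxidative phosphorylation genes (−0.14 to 0.017), ribosomal proteins (−0.36 to 0.19), lipid and cholesterol genes (−0.62 to 0.43) and oxidase and reactive oxygen defence genes (−0.11 to 0.89). Of 88 named genes, 80 never changed direction, and 11 of 1299 comparisons did. Those that turned with 1 array left out were Adgre1 (−0.27 to 0.82), Clec4f (−0.99 to 0.80), Igha (−0.48 to 3.18), Cyp2e1 (−0.27 to 1.24), Col1a1 (−0.060 to 0.74), Hgf (−0.49 to 0.83), Cxcr4 (−0.98 to 2.14) and Mki67 (−1.46 to 1.67), and Hgf was at −0.077 as the mean of its probe sets. The cause was not tested beyond the array left out. Signals near background limit the folds: 1262 genes were at background on 1 PBS array and 152 on both with G-CSF above it.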

Other observations

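All tests of this part were chosen after the results were seen, and its genes were picked after their values were seen.

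PBS replicate 1 held high signals of genes known from developing T cells. Rag1, a recombinase of lymphocyte precursors, had a signal of 6016 there and 1.61 to 2.20 elsewhere, and Dntt, terminal transferase, 20056 against 17.2 to 94.0. Ccr9, a homing receptor of thymocytes, had 8433 against 81.7 to 118, Bcl11b, a factor of T lineage commitment, 18671 against 190.0 to 375, and Lef1 5167 against 49.1 to 126. Of 23 T cell precursor genes, 21 lay more than 2-fold above all other arrays, with a median of 3.74 over their mean. Of 8 mature T cell genes, 2 lay more than 2-fold above, Icos at 1736 against 131 to 283 and Ctla4 at 1103 against 29.9 to 102, and the list median was −0.60. The other 6 lay lower than the mean of the other arrays: S1pr1 at −0.94, Klf2 at −0.89, Il7r at −0.51, Cd44 at −1.497, and Foxp3 and Cd40lg, both below the filter, at −0.70 and −0.32. Of 6 B cell precursor genes 0 lay more than 2-fold above, with a median of −0.98. The precursor list shares Cd3d, Cd3e, Cd3g, Thy1, Bcl11b, Themis and others with the fixed list of T cell markers. Of the mature list, Klf2 is also an immediate early gene and Cd44 also an adhesion molecule in the lists of the report. These counts alone thus do not tell T cell precursors from mature T cells.

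The first pattern weighed was these T cell precursor transcripts in PBS replicate 1 alone. Degradation of its RNA beyond that of all other arrays is argued against by the Gapdh 3' to 5' ratio of 15.7, below the 20.2 of the highest other array. The ratio lay above the 14.8 of PBS replicate 2, so degradation shared by the arrays is not excluded. A swap with a G-CSF sample is argued against by the primary granule list, which lay 4.48 lower in PBS replicate 1 than in the G-CSF arrays. The values show high T lineage transcripts on that array, but whether cells of the T lineage brought them remains open. Of T cell list members outside the precursor list, 8 of 10 lay more than 2-fold above all other arrays. These are among the 15 given in the report and add no independent evidence. Whether such cells were in the liver or their RNA was added later, and whether the label is right, was not tested.

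The second pattern was the rise of neutrophil granule and receptor transcripts with G-CSF. PBS replicate 1 as the sole source is argued against, since the lowest of the 3 list medians was 3.33 against PBS replicate 2 alone. The scaling of the arrays is argued against, since after quantile normalization the lowest of these medians lay 2.53 above the highest of the other 36 lists, while a factor per array moves all lists alike. Immature granulocytes among the cells of the G-CSF samples, which divide, are left undecided. The cell cycle list lay at −1.65 against PBS replicate 1 and 1.25 against PBS replicate 2. PBS replicate 1 had high cell cycle signals of its own, with a median of 3148 against 885 and 949 in the G-CSF arrays. Its value thus cannot speak on granulocytes, which leaves only the comparison with PBS replicate 2. The number of cells and the expression per cell were not measured.

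The third pattern was the lower level of genes of most other cell types in PBS replicate 1. The scaling of the arrays is argued against, since a factor per array moves all lists alike, while after quantile normalization the respiratory chain list lay 0.92 above the median of the 16 cell type lists, and above each of them. Dilution by RNA of other cells is left undecided: 15 of 16 cell type lists lay between 0.5 and 1.5 below the other arrays, a range set after the values were seen, and the erythroid genes lay outside it at −0.42. The T cell and neutrophil lists were not counted.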
